A study of Mus musculus with 8 samples.

How the data were processed

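RNA sequencing libraries from 8 mice were compared, 4 wildtype (C57Bl6/J) and 4 Has-tKO. Per the labels' protocols, mesenchymal stem cells (MSc) were taken from the long bones of the hind legs, grown for 4 passages, exposed to 4-hydroxytamoxifen for 48 h in passages 2 and 3, and sampled on day 7 of osteogenic culture. Per the labels' protocols, ribosomal RNA was removed from 100 ng RNA, and the remainder was reverse transcribed, made double-stranded and fragmented by Nextera tagmentation, a library type that does not record the strand. Each library came from a separate mouse, and each group has 4 replicates.

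The deposited table holds FPKM values (fragments scaled to transcript length and library size) for 8 libraries and 76557 loci, of which 50310 carry an identifier of the StringTie kind and 26247 an Ensembl identifier. Per the submitters' processing notes, the authors used bcl2fastq, fastp, HISAT2, StringTie and DESeq2, with the builds GRCm39 and hg38. The versions, the options, the role of hg38 and the way transcripts were combined into 1 value per locus are not given in the sources used here. Each column was assigned to its library by the name in the header, per the file headers, and no column of other samples was used.

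No read counts were used. A count-based test had been planned, and because the values are FPKM it was replaced by the fallback written beside it before the data were examined. The gene lists, the rule for named genes, the main tests and most alternatives were fixed at that same point. Low values were inspected for whole multiples of the worth of 1 read. At the best step size per library, 12.7% to 14.9% of low values lay within 0.05 of a whole multiple, where chance gives 10%. The sequencing depth is therefore unknown, and no counting error can be given for any value. The columns summed to between 198221 and 259871 FPKM.

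A gene name stands beside 49868 loci, and 26689 have none. Loci without a name held 45.4% to 61.5% of the FPKM of a library, and they were left out of the comparison of genes and counted apart. Where several loci shared a name (67 names on 153 loci), the gene lists used the locus with the highest mean. Names were taken from the table alone and never from the order of loci. Has1, Has2, Sp7, Col1a1, Spp1 and Bglap were not analysed here, because no locus in the table carries these names. Of the 1275 genes in the fixed lists, 207 carried no name in the table. A merged locus can hold reads of neighbouring or antisense genes, and levels of different genes should not be set against each other: Gapdh was listed at 9.20 FPKM and Eef1a1 at 910 FPKM in wildtype.

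Values were transformed as log2(FPKM + 1). Named loci with at least 1 FPKM in at least 4 libraries were tested, which left 9916 genes. A linear model with genotype was fitted with limma 3.58.1 (empirical Bayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The log2 fold change is Has-tKO minus wildtype on the log2(FPKM + 1) scale, which understates the change of genes near or below 1 FPKM. The fallback named no rescaling between libraries, and none was applied. The planned count-based test had included one. The median log2 fold change over all tested genes was then 0.16, and median-ratio size factors computed on the FPKM of 7435 loci brought it to 0.01. For this reason the value after scaling is given beside the unscaled one, and medians of gene lists are given relative to the median of all tested genes.

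There were 48 fixed lists of pathway genes and cell type markers, and the 43 with at least 5 tested members were tested with camera (preset inter-gene correlation 0.01), with camera and an estimated correlation, and with fry, which tests against no change rather than against other genes. Adjustment was over the 43 lists. Members that passed were counted after adjustment over all tested genes and after adjustment within each list. A score per library is the mean log2(scaled FPKM + 1) of the tested members minus the wildtype mean. Changed genes within 10 Mb of Has1, Has2 and Has3 were compared with all others by Fisher's exact test. Gene positions came from the GENCODE M21 annotation of GRCm38 and served only for chromosome and neighbourhood. A position was found for 96.9% of named loci.

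The named genes are the targeted genes, 10 anchor genes of bone, cartilage and fat (6 of them named in the table), the 8 higher and 8 lower genes with the largest change among those that passed, had a mean of at least 1 FPKM, did not overlap between the groups and had an established symbol, and up to 4 members with the smallest p from each described list. Genes outside this rule, such as Tgfbi, Nid1, Efemp2, Klf15, Alcam, Clec7a, Cybb, Gbp5, Efnb2, Cd59a and Itga4, were chosen after their values were seen, because a count of 5 or fewer includes them or a call depends on the scaling.

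The fitting code was tested on simulated data for the comparison of Has-tKO with wildtype: 9916 genes, 200 of them changed. It recovered 57.0% of genes changed 2-fold and 98.0% of those changed 4-fold, and 3.73% of its calls were false. The simulated noise was normal and independent between genes, with no shift between libraries and no library standing apart. Changes were placed only in genes above a set mean level. These shares check the code and need not hold for the real libraries. Alternatives covered the scaling, the filter, the pseudocount, library quality weights (limma's array weights, in place of voom, which needs counts), the replicate number as a block, each library left out in turn, the threshold, the set test and the window around the targeted loci. Data handling used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.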

Results

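Hyaluronan is a large glycosaminoglycan of the extracellular matrix, made at the cell membrane by the synthases Has1, Has2 and Has3. The study asked how loss of all 3 enzymes bears on the osteogenic differentiation of mesenchymal stem cells (MSc). MSc of 4 wildtype and 4 Has-tKO mice were exposed to 4-hydroxytamoxifen, differentiated for 7 days and profiled by RNA sequencing after ribosomal RNA depletion. Has-tKO mice carry constitutive deletions of Has1 and Has3 and a deletion of Has2 that 4-hydroxytamoxifen induces. Levels are FPKM as deposited, given as mean ± SD with n = 4 per genotype, and the sequencing depth is unknown.

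Between 8327 and 10357 named genes per library reached 1 FPKM. Wildtype libraries held 9440 ± 748 such genes and Has-tKO libraries 10212 ± 143 (exact permutation p = 0.0286, two-sided, the smallest possible with 4 against 4). Wildtype 1 stood apart, with 8327 such genes and 61.5% of its FPKM on loci without a gene name, where the other wildtype libraries had 45.4% to 47.9%. The single locus with the highest mean held 30.4% of the FPKM of wildtype 1, against 14.2% to 18.4% in the other wildtype libraries. The percentage on unnamed loci alone therefore does not show a shift of many loci. The size factor of wildtype 1 was 0.684, against 0.990 to 1.11 in the other 7 libraries. Has-tKO 4 had 56.4% of its FPKM on such loci. The first principal component of the 500 most variable genes held 51.1% of their variance and placed the 4 wildtype libraries (-21.7 to -1.13) below the 4 Has-tKO libraries (14.7 at most). The second held 20.5%, with Has-tKO 4 at one end (15.7). The mean correlation of log2 values with the other libraries of the same genotype was 0.916 for wildtype 1 and 0.940 to 0.962 for the other 7.

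**Figure D1:**
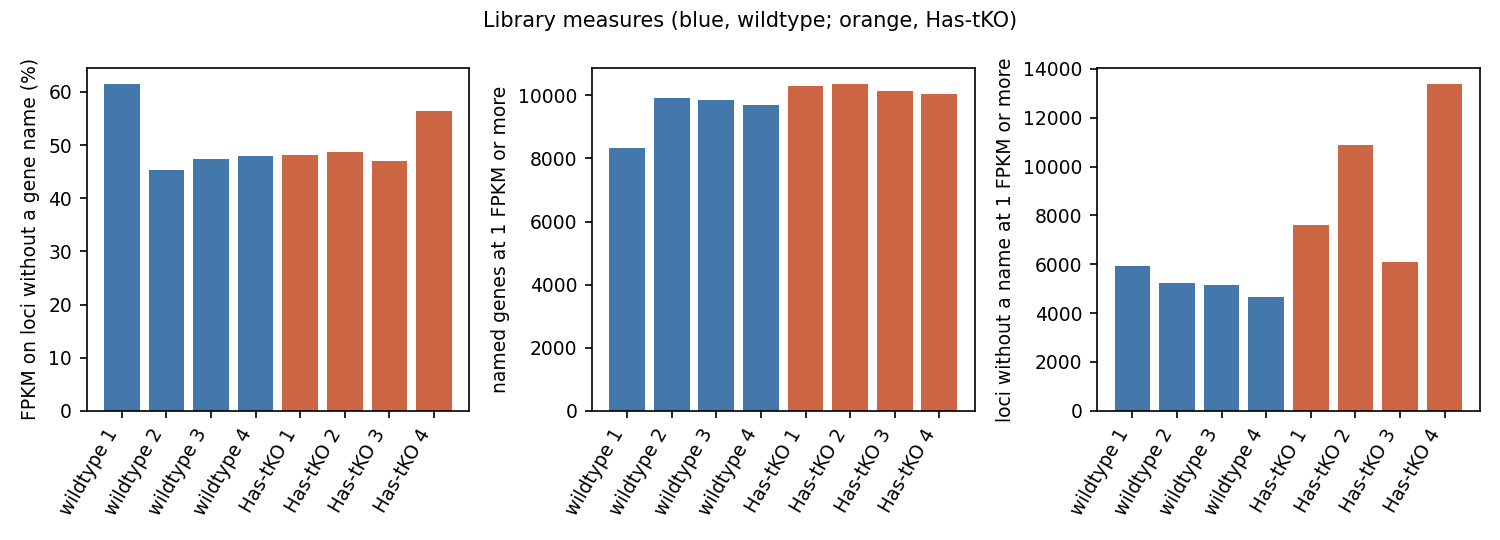
Bars show, for each of the 8 libraries, the percentage of FPKM on loci without a gene name, the number of named genes at 1 FPKM or more, and the number of loci without a name at 1 FPKM or more (blue, wildtype; orange, Has-tKO). Wildtype 1 has 61.5% of its FPKM on unnamed loci and 8327 named genes, and Has-tKO 4 has 13374 unnamed loci.

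Of the targeted genes only Has3 carried a name in the table, at levels too low for the test: 0.378 ± 0.0995 FPKM in wildtype and 0.503 ± 0.238 FPKM in Has-tKO (exact permutation p = 0.371, two-sided). No decrease of Has3 was detectable at these levels. Which part of Has3 is deleted is not given in the sources used here, so its transcript level checks no label, and wildtype and Has-tKO name libraries by their labels throughout. Has2os, a transcript antisense to Has2 whose reads cannot be separated from Has2 without strand information, lay at 0.639 ± 0.456 FPKM in wildtype and 0.682 ± 0.488 FPKM in Has-tKO (exact permutation p = 0.886). Xist, the transcript of the inactive X chromosome, was present in all 8 libraries (13.5 to 72.2 FPKM), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stayed at or below 0.0806 FPKM.

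Ccl2, a chemokine that attracts monocytes, rose from 7.32 ± 2.53 FPKM in wildtype to 42.5 ± 12.1 FPKM in Has-tKO (log2 fold change 2.40, SE 0.27, limma adjusted p = 0.00226). The chemokines Ccl3 (1.85) and Ccl4 (1.97), the myeloid receptors Fcrls (2.20) and Clec4e (1.86), the oxysterol-producing enzyme Ch25h (1.98) and the transcription factor Egr2 (1.93) also rose. Hmga1b rose as well (1.90), but it is a near-identical copy of Hmga1 and its level is uncertain. Car9, a carbonic anhydrase induced by hypoxia, fell by 1.53 on the log2 scale, from 18.7 ± 9.41 to 5.45 ± 1.82 FPKM (SE 0.34, adjusted p = 0.0462), and did not pass after median-ratio scaling (-1.72, adjusted p = 0.0723). The secreted protease inhibitor Slpi (-1.44), Otor (-1.10), the acid-sensing channel Asic3 (-1.08), Col10a1 (-1.06), Fibin (-1.05), the thyroid hormone deiodinase Dio2 (-1.04) and B3gnt3 (-1.04) fell. These 7 genes and the 8 that rose passed after scaling too.

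In all, 176 of 9916 genes changed, 157 higher and 19 lower in Has-tKO (89.2% higher), and 114 of them changed at least 2-fold (104 higher, 10 lower). After median-ratio scaling 280 genes changed, 172 higher and 108 lower (61.4% higher), of which 147 were among the 176, and 94 changed at least 2-fold (67 higher, 27 lower). With wildtype 1 and Has-tKO 4 both left out, 320 genes changed without scaling (233 higher, 87 lower) and 265 with it (150 higher, 115 lower). Without 1 library the count was 349 (wildtype 1), 77 (wildtype 2), 348 (wildtype 3), 10 (wildtype 4), 5 (Has-tKO 1), 61 (Has-tKO 2), 68 (Has-tKO 3) and 40 (Has-tKO 4). The 5 genes were Hmga1b, Rnps1-ps, Ccl2, Nfkbie and Egr1, of which Rnps1-ps and Nfkbie were named after their values were seen. Of 51 named genes that passed, Ccl2, Egr1 and Hmga1b passed in each of these 8 fits, and 13 of the 51 passed in 6 or more.

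**Figure D2:**
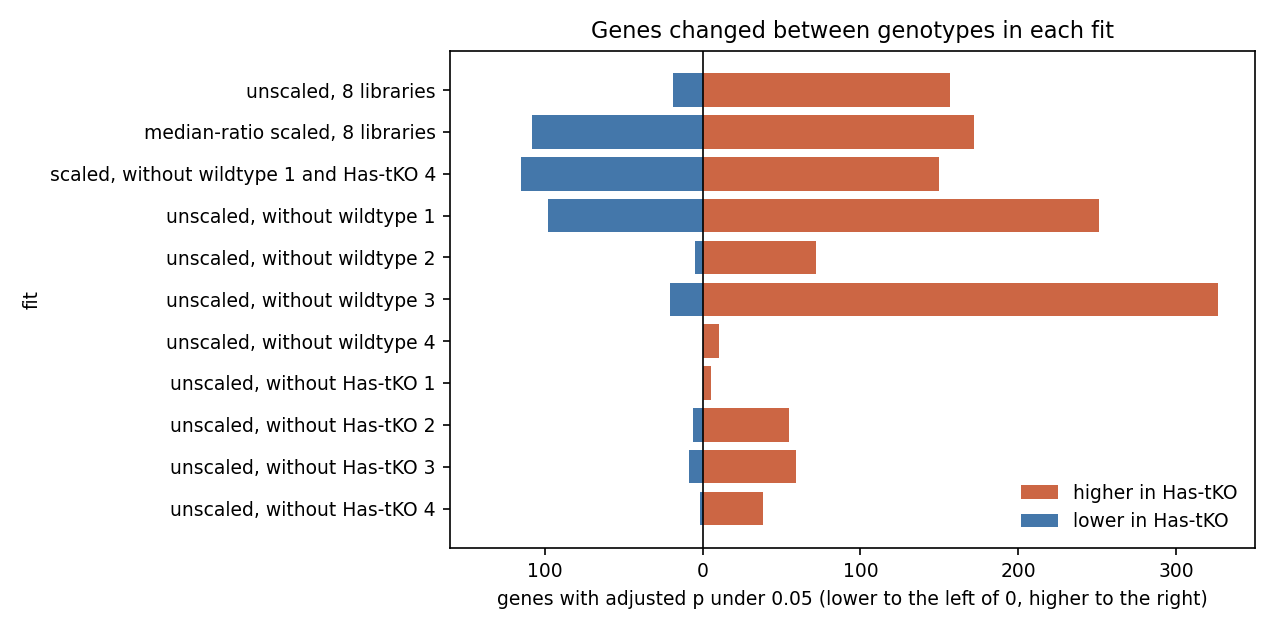
Horizontal bars give the number of genes with adjusted p under 0.05 in each fit, lower in Has-tKO to the left of 0 (blue) and higher to the right (orange). The unscaled fit of 8 libraries has 157 higher and 19 lower genes, the scaled fit 172 and 108, and the unscaled fits without 1 library range from 5 to 349 genes in all.

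Some genes of inflammatory signalling were higher in Has-tKO. Of 24 tested members of the NF-kappaB and cytokine list, 12 rose and none fell, and 18 rose and 1 fell when adjusted over the list alone. The neutrophil chemokine Cxcl2 went from 0.257 ± 0.0843 to 3.14 ± 0.485 FPKM (log2 fold change 1.72, SE 0.15, adjusted p = 0.000635). The adhesion molecule Icam1 went from 12.2 ± 2.62 to 35.4 ± 5.81 FPKM (1.48, SE 0.19, adjusted p = 0.00633), and Nfkb2, an NF-kappaB subunit that is itself an NF-kappaB target, from 12.4 ± 1.51 to 28.5 ± 2.33 FPKM (1.14, adjusted p = 0.00778). The median of the list lay 0.69 above that of all tested genes (camera adjusted p = 3.4e-13), and the call was lost at adjusted p = 0.608 with an estimated correlation. After scaling 13 members rose and none fell. The immediate early list, genes induced within minutes of a stimulus, had 9 of 21 tested members higher and none lower, and 14 higher when adjusted over the list alone. Egr1 rose from 1.93 ± 0.866 to 8.07 ± 0.825 FPKM (1.68, SE 0.22, adjusted p = 0.00633), with Junb (1.27) and Egr3 (1.14). Its median lay 0.58 above that of all tested genes (camera adjusted p = 2.6e-12, adjusted p = 0.227 with an estimated correlation), and 9 members rose after scaling too.

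Markers of macrophages and other myeloid cells moved with the genotype, and this measured fact stands beside every gene group described here. Of 21 tested markers 3 rose: the fractalkine receptor Cx3cr1 (1.99 ± 1.23 to 6.15 ± 1.16 FPKM, log2 fold change 1.35, SE 0.28, adjusted p = 0.0371), the leukocyte surface protein Cd52 (0.87, adjusted p = 0.0454) and the myeloid transcription factor Spi1 (1.06, adjusted p = 0.0458). After scaling 3 passed again, Cx3cr1 (adjusted p = 0.0334), the lectin receptor Clec7a (1.12, adjusted p = 0.0432) and the oxidase subunit Cybb (1.20, adjusted p = 0.0468), while Cd52 (0.71, adjusted p = 0.112) and Spi1 (0.88, adjusted p = 0.0535) did not. When adjusted over the list alone all 21 were higher, and 16 after scaling. The median lay 0.85 above that of all tested genes (camera adjusted p = 3.9e-13, adjusted p = 0.608 with an estimated correlation). The score of the list was 0.49 to 1.10 in the Has-tKO libraries and -0.24 to 0.42 in the wildtype libraries, the highest of these being wildtype 3. All 21 markers had a mean of at least 1 FPKM in wildtype, and 2 also belong to another list.

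**Figure D3:**
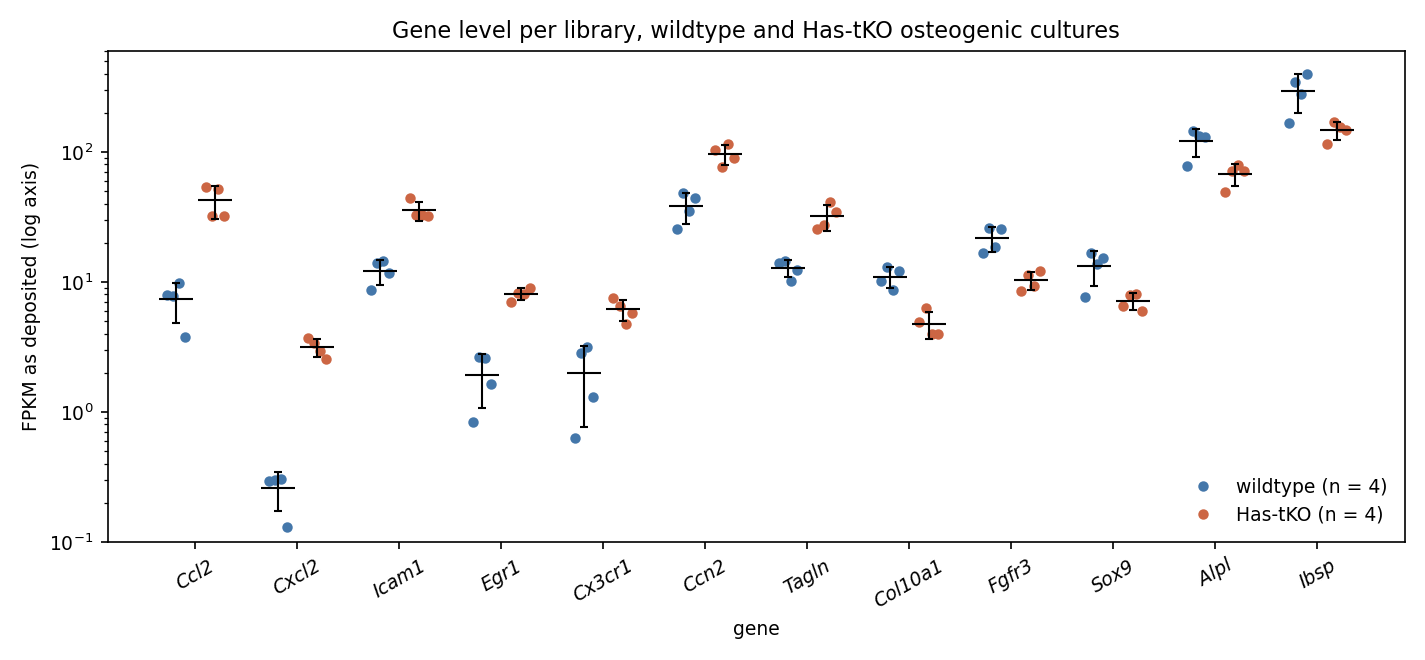
Points are FPKM values of single libraries on a log axis for 12 genes (blue, wildtype; orange, Has-tKO), and black bars give the mean ± SD of 4 libraries. Ccl2 goes from 7.32 to 42.5 FPKM and Cxcl2 from 0.257 to 3.14 FPKM, while Fgfr3 goes from 21.6 to 10.3 FPKM and Alpl from 121 to 67.4 FPKM, the latter without passing the unscaled test.

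Some cartilage genes were lower in Has-tKO. Of 14 tested chondrocyte markers 3 fell: Col10a1, the collagen of hypertrophic cartilage, to 4.78 ± 1.11 FPKM (log2 fold change -1.06, SE 0.19, adjusted p = 0.0203), the growth factor receptor Fgfr3 from 21.6 ± 4.62 to 10.3 ± 1.67 FPKM (-0.99, SE 0.19, adjusted p = 0.0265), and Col9a1 from 5.12 ± 0.644 to 2.38 ± 0.943 FPKM (-0.89, adjusted p = 0.0488). Sox9, the transcription factor of cartilage, had 13.3 ± 3.98 and 7.11 ± 1.04 FPKM (-0.78, adjusted p = 0.0966) and fell after scaling (-0.96, SE 0.13, adjusted p = 0.0118). When adjusted over the list alone 10 members fell and none rose, with and without scaling. The median of the list lay -0.87 from that of all tested genes (camera adjusted p = 3.4e-13, adjusted p = 0.0551 with an estimated correlation). Without wildtype 1 that median was -0.58, and the myeloid score was higher in the same 4 Has-tKO libraries.

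For osteoblast genes the unscaled and the scaled fits differed. Alkaline phosphatase (Alpl), an enzyme of early mineralization, had 121 ± 29.3 FPKM in wildtype and 67.4 ± 12.8 FPKM in Has-tKO (log2 fold change -0.82, SE 0.22, adjusted p = 0.0826), and fell after scaling (-1.02, SE 0.15, adjusted p = 0.0154). Bone sialoprotein (Ibsp) had 296 ± 97.9 and 147 ± 22.6 FPKM (-0.95, SE 0.25, adjusted p = 0.0718), and fell after scaling (-1.16, SE 0.18, adjusted p = 0.0177). The sphingomyelinase Smpd3, needed for mineralization, behaved alike (-1.07, adjusted p = 0.0580, and after scaling -1.26, adjusted p = 0.0210), but it lies within 10 Mb of the engineered Has3 locus. Runx2, the master transcription factor of the osteoblast lineage, passed in neither fit (5.95 ± 1.82 and 4.47 ± 0.731 FPKM, -0.31, adjusted p = 0.489, and after scaling -0.48, adjusted p = 0.110). Of 18 tested members of the osteoblast matrix and mineralization list, 1 rose, the phosphate transporter Slc20a1 (1.06, adjusted p = 0.0268), and none fell, against 1 higher and 5 lower after scaling and 1 higher and 4 lower when adjusted over the list alone (2 and 7 after scaling). Of 17 tested members of the osteoblast commitment list, Fam20c, a kinase of secreted matrix proteins, rose (0.97, adjusted p = 0.0152) and Fgfr3 fell, with 1 higher and 3 lower after scaling and 1 higher and 2 lower when adjusted over the list alone (1 and 5 after scaling). Both lists had a median -0.25 from that of all tested genes (camera adjusted p = 0.00231 each, adjusted p = 0.916 with an estimated correlation). The median of the matrix and mineralization list was -0.16 without wildtype 2 and -0.17 without wildtype 4. Myeloid markers moved the opposite way in the same libraries. Without wildtype 1 the unscaled fit passed Alpl (-1.01, adjusted p = 0.0169) and Ibsp (-1.20, adjusted p = 0.00998). Neither gene passed the unscaled fit with all 8 libraries, nor when any other single library was left out. With 1 of those other libraries left out, the lowest adjusted p was 0.118 for Alpl (without Has-tKO 3) and 0.0889 for Ibsp (without wildtype 3). These omissions were made without scaling and do not test the scaled fit, in which both genes passed.

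Fat markers did not move as a group. Of 19 tested adipocyte markers the transcription factor Cebpd rose (8.19 ± 0.458 to 13.4 ± 0.879 FPKM, log2 fold change 0.65, SE 0.14, adjusted p = 0.0442), without passing after scaling (0.46, adjusted p = 0.120), and 5 were higher and 1 lower when adjusted over the list alone, against 3 and 3 after scaling. After scaling 1 marker fell, Klf15 (-0.79, adjusted p = 0.0310). Pparg, the master regulator of fat cells, had 2.17 ± 0.717 and 2.73 ± 0.424 FPKM (0.26, adjusted p = 0.510). Apoe, a lipid carrier that macrophages also make, had 22.7 ± 8.83 and 55.1 ± 18.7 FPKM (1.26, adjusted p = 0.0550). Camera gave an adjusted p of 0.709 for the list. Among 17 tested genes of hyaluronan breakdown and binding none rose or fell, and 1 was higher and 1 lower when adjusted over the list alone (1 and 3 after scaling). The unscaled ones were the scavenger receptor Stab1 (1.35, adjusted p = 0.0781) and Susd5 (-0.72, adjusted p = 0.106), the latter passing after scaling (-0.91, adjusted p = 0.0430). Cd44, the main hyaluronan receptor, had 25.7 ± 9.15 and 40.5 ± 6.91 FPKM (0.69, SE 0.26, adjusted p = 0.193). Camera gave an adjusted p of 0.598 for the list, and 0.990 and 0.829 for the lists of sugar nucleotide supply (17 tested) and sulfated glycosaminoglycan assembly (28 tested), in which no member changed over all genes and 1 sulfated glycosaminoglycan gene was higher when adjusted over the list alone (0 after scaling).

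**Figure D4:**
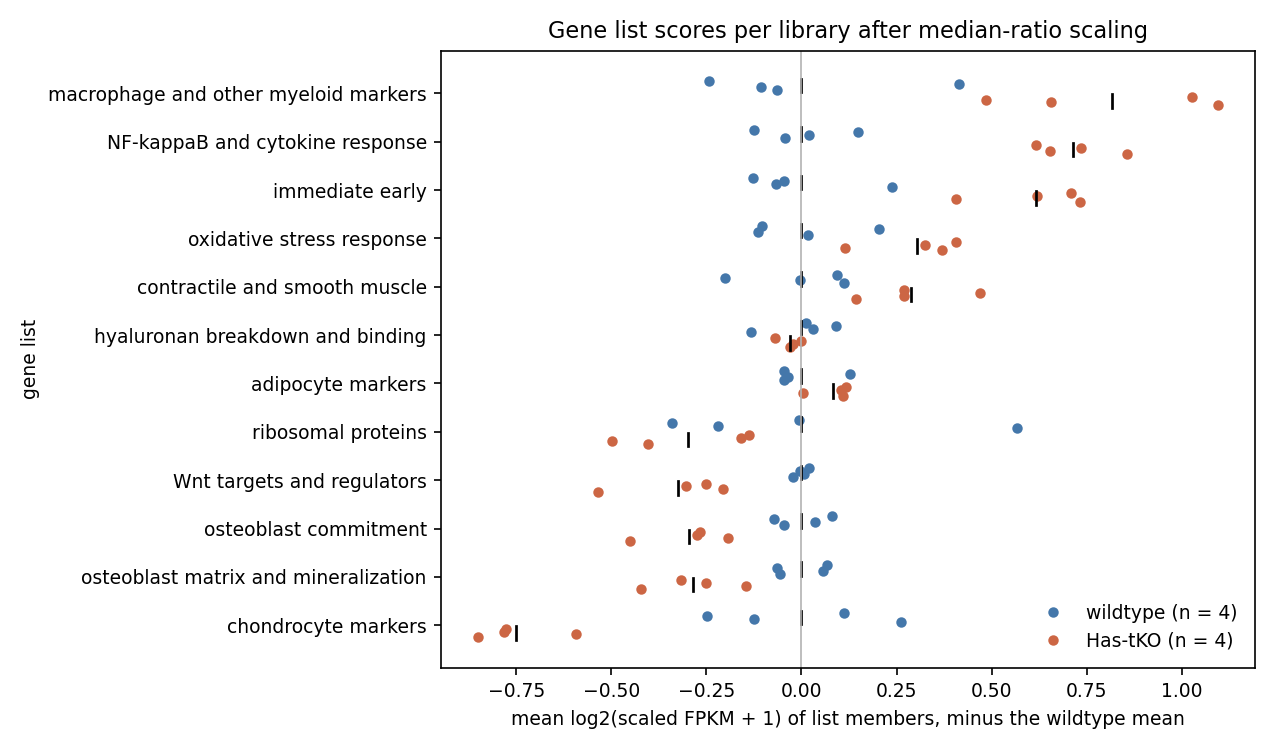
Each point is the score of a gene list in 1 library, the mean log2(scaled FPKM + 1) of its members minus the wildtype mean (blue, wildtype; orange, Has-tKO), and black ticks are group means of 4 libraries. The myeloid score is 0.49 to 1.10 in the Has-tKO libraries and -0.24 to 0.42 in the wildtype libraries, and the chondrocyte score is -0.85 to -0.59 and -0.25 to 0.26.

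Some contractile and matrix genes were higher in Has-tKO. Ccn2, a matricellular protein induced by TGF-beta and by mechanical load, rose from 38.3 ± 10.2 to 96.3 ± 16.5 FPKM (log2 fold change 1.33, SE 0.22, adjusted p = 0.0156), and the actin-binding protein Tagln from 12.8 ± 1.95 to 32.0 ± 7.25 FPKM (1.25, SE 0.19, adjusted p = 0.0136). Of 20 tested contractile and smooth muscle genes 2 rose, Tagln and the smooth muscle actin Actg2 (1.44, adjusted p = 0.0333), and 4 were higher when adjusted over the list alone, against 5 higher and 1 lower after scaling (median 0.24 above all tested genes, camera adjusted p = 0.00226, adjusted p = 0.916 with an estimated correlation). Of 21 tested TGF-beta targets 4 rose (Tagln, Ccn2, Col4a1 and Col4a2), and 9 were higher and 2 lower when adjusted over the list alone, while camera gave an adjusted p of 0.178. After scaling 2 TGF-beta targets rose (Tagln and Ccn2) and 2 fell, Tgfb2 (adjusted p = 0.0339) and Tgfbi (-0.87, adjusted p = 0.0198), and 7 were higher and 2 lower when adjusted over the list alone. Of 30 tested fibrillar and basement membrane matrix genes Col8a1 (1.35, adjusted p = 0.0136), Col4a1 (0.78, adjusted p = 0.0268) and Col4a2 (0.71, adjusted p = 0.0395) rose, and 7 were higher when adjusted over the list alone (camera adjusted p = 0.442). After scaling 2 rose, Col8a1 and Nid1, and 2 fell, Tgfbi and Efemp2, while Col4a1 (adjusted p = 0.0989) and Col4a2 (adjusted p = 0.138) did not pass, and 7 were higher and 8 lower when adjusted over the list alone. Of 29 tested matrix proteases and inhibitors Adamts5, an aggrecan-degrading protease, rose (0.97, adjusted p = 0.0295) and the serine protease Htra1 fell (-0.96, adjusted p = 0.0241), the same 1 and 1 being counted when adjusted over the list alone, against 2 higher and 9 lower after scaling (median -0.19 from all tested genes, camera adjusted p = 0.0313, adjusted p = 0.916 with an estimated correlation). Proteoglycan core proteins (17 tested, median -0.29, camera adjusted p = 0.00853, adjusted p = 0.916 with an estimated correlation) had no changed member, and 1 lower when adjusted over the list alone, Kera, a cornea and bone proteoglycan (-0.90, adjusted p = 0.0550), which fell after scaling (-1.05, adjusted p = 0.0215), when 2 were lower within the list. The median was -0.15 without wildtype 2 and -0.19 without Has-tKO 1, and the list was not called without Has-tKO 4 (camera adjusted p = 0.0704). The protease list was not called without wildtype 2 (camera adjusted p = 0.0707), wildtype 3 (0.0746), Has-tKO 1 (0.0507) or Has-tKO 4 (0.105). The myeloid markers were higher in the same libraries.

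Among signalling lists, Wnt targets and regulators had a median -0.30 from all tested genes (18 tested, camera adjusted p = 3.0e-05, adjusted p = 0.916 with an estimated correlation) and BMP targets and regulators -0.28 (18 tested, camera adjusted p = 0.00792, adjusted p = 0.916 with an estimated correlation). No member of either changed without scaling, over all genes or when adjusted over the list alone. After scaling 1 Wnt gene was higher and 8 lower, and 3 BMP genes lower, when adjusted over the list alone. Over all genes 3 Wnt genes fell after scaling, the ligand Wnt16 (-0.72, adjusted p = 0.0432) and the receptors Fzd8 (-0.81, adjusted p = 0.0343) and Fzd2 (-0.72, adjusted p = 0.0312). Likewise 2 BMP genes fell, Bmper (-0.78, adjusted p = 0.0132) and Atoh8 (-0.73, adjusted p = 0.0310). Of 8 tested Notch targets and receptors the target Hes1 rose (0.310 ± 0.215 to 1.40 ± 0.335 FPKM, log2 fold change 0.88, SE 0.18, adjusted p = 0.0344), and 5 were higher when adjusted over the list alone, 4 after scaling (median 0.29 above all tested genes, camera adjusted p = 0.0380, adjusted p = 0.916 with an estimated correlation). After scaling 3 Notch genes rose over all genes, Hes1, the ligand Jag1 (0.61, adjusted p = 0.0343) and the receptor Notch1 (0.68, adjusted p = 0.0432). The Notch list was not called without wildtype 2 (camera adjusted p = 0.0924), Has-tKO 1 (median 0.16, 0.201), Has-tKO 2 (median 0.16, 0.198), Has-tKO 3 (0.188) or Has-tKO 4 (0.101). These libraries also differed in myeloid score, as given above.

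Antioxidant genes were higher in part. Of 29 tested oxidative stress genes 4 rose: the cystine transporter Slc7a11 (1.54 ± 1.20 to 5.32 ± 0.748 FPKM, log2 fold change 1.42, SE 0.27, adjusted p = 0.0268), Gclc, an enzyme of glutathione synthesis (1.13, adjusted p = 0.0404), the mitochondrial superoxide dismutase Sod2 (0.99, adjusted p = 0.0404) and the metallothionein Mt2 (1.40, adjusted p = 0.0472, and 0.0975 after scaling). When adjusted over the list alone 11 were higher, against 9 higher and 1 lower after scaling (median 0.31 above all tested genes, camera adjusted p = 0.00231, adjusted p = 0.916 with an estimated correlation). Of 28 tested glycolysis and hypoxia genes Car9 fell and the hexokinase Hk2 rose (0.74, adjusted p = 0.0478), also when adjusted over the list alone. Over all genes neither passed after scaling, while 1 member was higher and 1 lower when adjusted over the list alone. The list had a median -0.14 from all tested genes (camera adjusted p = 0.0313, adjusted p = 0.916 with an estimated correlation). The list was not called without wildtype 1 (median -0.08, adjusted p = 0.285), wildtype 4 (0.0553), Has-tKO 2 (0.376) or Has-tKO 4 (0.108). Ribosomal protein genes (42 tested, median -0.27, camera adjusted p = 1.6e-06, adjusted p = 0.916 with an estimated correlation) had no changed member by either adjustment, as in the case of Rps9 (-0.70, adjusted p = 0.182). Without wildtype 1, whose score of 0.57 stood above the other libraries (-0.50 to -0.01), the median was -0.09 (camera adjusted p = 0.0361), and their many processed copies make single levels uncertain. Mitochondrially encoded genes (9 tested, median 0.32, camera adjusted p = 0.0487, adjusted p = 0.916 with an estimated correlation) had none either, and were not called without wildtype 1 (camera adjusted p = 0.0652), wildtype 2 (0.0579), Has-tKO 3 (0.220) or Has-tKO 4 (0.0675). Antigen presentation genes (18 tested, median 0.22, camera adjusted p = 0.0408, adjusted p = 0.916 with an estimated correlation) had no changed member and 2 higher when adjusted over the list alone, H2-D1 (178 ± 36.6 and 330.1 ± 77.7 FPKM, adjusted p = 0.0550) and H2-K1 (0.87, adjusted p = 0.0602), which share sequence with each other, and neither passed after scaling, within the list or over all genes. The list was not called after scaling (camera adjusted p = 0.0771). In the unscaled fit it was not called without wildtype 2 (camera adjusted p = 0.0509), wildtype 3 (0.103), wildtype 4 (0.131) or Has-tKO 1 (median 0.09, 0.249). Myeloid cells are rich in several of these transcripts, and the myeloid score was higher in each Has-tKO library than in each wildtype library.

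Camera, which sets a list against the other genes, called 17 of the 43 tested lists, none with an estimated correlation. Fry tests a list against no change and not against other genes, so without scaling it includes the overall shift. It called 4 lists without scaling: immediate early (adjusted p = 0.00345), NF-kappaB and cytokine response (0.0132), chondrocyte markers (0.0132) and glucocorticoid targets (0.0462). After scaling it called 10: NF-kappaB and cytokine response (0.00255), chondrocyte markers (0.00979), immediate early (0.0145), Wnt targets and regulators (0.0255), osteoblast matrix and mineralization (0.0255), Notch targets and receptors (0.0255), osteoblast commitment (0.0270), myeloid markers (0.0352), osteoclast-regulating factors (0.0448) and BMP targets and regulators (0.0462). Glucocorticoid targets did not pass after scaling (0.142). In the unscaled fit neither camera nor any member over all genes passed for the interferon response (29 tested, camera adjusted p = 0.604, Gbp5 1.05 with adjusted p = 0.0509, and 0.0478 after scaling), S phase (25 tested, 0.147), mitosis (26 tested, 0.864), cholesterol synthesis (23 tested, 0.598), the nuclear-encoded respiratory chain (30 tested, 0.366), stromal progenitors (22 tested, 0.501, Alcam 0.90 with adjusted p = 0.0550, and 0.0339 after scaling), skeletal muscle (8 tested, 0.177), sex-linked genes (5 tested, 0.990) and knockout and strain markers (5 tested, 0.178). Adjusted over the list alone, 1 interferon gene, 4 stromal progenitor genes and 2 knockout and strain markers were higher, and none in the other 6 lists. After scaling it was 1 interferon gene, 4 stromal progenitor genes with 1 lower, and 1 knockout and strain marker. The score of the knockout and strain list was 0.10 to 0.42 in the Has-tKO libraries and -0.06 to 0.11 in the wildtype libraries. With 5 tested members, a difference of strain between the genotypes was not excluded. Lists with fewer than 5 tested members were not tested: hyaluronan synthases (0), Hedgehog targets (4), endothelial (3), blood cell (3) and glial and neural markers (4), in which no member changed over all genes.

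Genes next to an engineered locus can differ between strains because flanking DNA of the donor strain is carried along. Within 10 Mb of Has1 on chromosome 17, 5 of 131 tested genes changed (Abca3, Dusp1, Msrb1, Sod2 and Tnfrsf12a), or 3.82% against 1.76% of all other genes (Fisher's exact p = 0.0852, adjusted p = 0.256). Near Has2 on chromosome 15 it was 1 of 32 (Ccn3, Fisher's exact p = 0.439), and near Has3 on chromosome 8 it was 0 of 93 (Fisher's exact p = 0.417, adjusted p = 0.439). After scaling it was 4 of 131 near Has1 (Abca3, Cacna1h, Sod2 and Tnfrsf12a), 1 of 32 near Has2 (Ccn3) and 2 of 93 near Has3 (Mtss2 and Smpd3), with Fisher's exact p = 0.789, 0.603 and 1. These genes were named after their values were seen. At an unadjusted p under 0.05 the test called 1657 genes in all.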

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

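In this part the share of loci seen in a single library was computed only after the number of unnamed loci had been seen, and the test of silent genes was written before its result. Among 232 groups of 4 libraries checked for a value standing apart, 17 were found where chance gives 11.6, about 1 in 20 groups.

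Unnamed loci at 1 FPKM or more numbered 9480 ± 3278 in Has-tKO and 5249 ± 527 in wildtype (exact permutation p = 0.0286, two-sided, n = 4 each), with 13374 in Has-tKO 4 and 10872 in Has-tKO 2. Of the excess of these 2 libraries over the wildtype mean, 61.2% reached 1 FPKM in that library alone, which is consistent with loci assembled from a single library. Genes silent in this cell type had a mean of 0.00539 FPKM in Has-tKO 4, within the range of the wildtype libraries (0.00269 to 0.00565). The groups had 0.00636 ± 0.00201 and 0.00423 ± 0.00124 FPKM (Has-tKO and wildtype, exact permutation p = 0.114), so genomic DNA as the cause is left open. Of 4506 unnamed loci that could be tested by limma, 42 rose and 1 fell, and after scaling 45 rose and 15 fell, and a true rise of some transcripts remains untested.

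Wildtype 1 had 61.5% of its FPKM on unnamed loci, against 45.4% to 47.9% in the other wildtype libraries. A single locus held 30.4% of its FPKM, against 14.2% to 18.4%. Wildtype 1 had 8327 named genes at 1 FPKM or more, against 9679 to 9906. Fzd1 was at 18.9 FPKM in wildtype 1, against 38.5 to 40.2 FPKM. Rps4x was at 347 FPKM in wildtype 1, against 149 to 181 FPKM. Slpi was at 23.2 FPKM in wildtype 1, against 14.8 to 15.7 FPKM. Zyx was at 5.95 FPKM in wildtype 1, against 9.14 to 9.42 FPKM.

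In wildtype 3 Cebpd was at 8.87 FPKM, against 7.93 to 7.99 FPKM in the other wildtype libraries. Fcrls was at 28.9 FPKM in wildtype 3, against 9.89 to 11.4 FPKM. Junb was at 19.1 FPKM in wildtype 3, against 14.8 to 15.1 FPKM. Stab1 was at 67.2 FPKM in wildtype 3, against 19.7 FPKM at the lowest. The adipocyte score was 0.13 in wildtype 3, against -0.05 to -0.04. In wildtype 4 Cxcl2 was at 0.131 FPKM, against 0.295 to 0.306 FPKM, and Fibin was at 3.56 FPKM, against 2.68 to 2.81 FPKM.

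Has3 was at 0.150 FPKM in Has-tKO 4, against 0.576 to 0.663 FPKM in the other Has-tKO libraries. Icam1 was at 44.1 FPKM in Has-tKO 1, against 32.3 to 32.7 FPKM. Mmp9 was at 12.6 FPKM in Has-tKO 3, against 5.05 to 5.88 FPKM. The adipocyte score was 0.00469 in Has-tKO 2, against 0.10 to 0.12.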

How the results depend on the processing

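The alternatives named TMM, unnamed loci tested together, myeloid covariate, and scaling or omission in combination were chosen only after the values had been seen. Limits hold for all values: n = 4 per genotype, FPKM without read counts and with unknown depth, no name for many loci, and no DESeq2 Wald test, which was not run because it needs counts. Against 176 changed genes (157 higher, 19 lower, 114 at least 2-fold), the cause of the following shifts was not tested.

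Median-ratio scaling gave 280 changed genes (172 higher, 108 lower), and TMM scaling 267 (166 higher, 101 lower). Without a filter 2 genes changed (Cxcl2 and Hmga1b), 2 higher, 0 lower and 2 at least 2-fold, with 2535 at an unadjusted p under 0.05. Library quality weights gave 766 (573 higher, 193 lower), and scaling with these weights 820 (469 higher, 351 lower). A pseudocount of 0.1 gave 111 (96 higher). With the replicate number as a block 147 changed, 123 of them among the 176, although 2 of 8 libraries were closest to the library of their own number, and scaling with this block gave 40 (24 higher, 31 at least 2-fold). Scaling without wildtype 1 gave 329 (143 lower), scaling without wildtype 1 and Has-tKO 4 gave 265 (115 lower, 63 at least 2-fold), and omission of both without scaling gave 320 (87 lower). An adjusted p under 0.01 left 11 genes, and a test against a fold of 1.5 left 6. With unnamed loci in the same test 94 named genes changed. With the mean of the myeloid markers as a covariate after scaling limma called 0 genes, with 211 at an unadjusted p under 0.05. The covariate had a correlation of 0.851 with genotype, so that a loss of calls was close to built in and the count says nothing about the cause.

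With 1 library left out, changed genes ranged from 5 (Has-tKO 1) to 349 (wildtype 1), higher genes from 5 to 327 (wildtype 3), lower genes from 0 (wildtype 4 and Has-tKO 1) to 98, and genes changed at least 2-fold from 5 to 220. Named genes that passed, 51 at first, ranged from 3 to 64. They were 2 without a filter, 83 with weights, 16 with scaling and block, and 79 with scaling and weights. In 792 comparisons of named genes with 1 library left out and 1211 under other settings no direction of a called gene reversed. Of the 176 changed genes, 174 did not overlap between the groups. For such genes leaving out 1 library cannot reverse the direction, so that part was fixed in advance.

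Called gene lists, 17 by camera, were 16 by camera after scaling, when antigen presentation was lost. They were 0 with an estimated correlation and 4 by fry (10 after scaling), which tests against no change. By fry the lists of matrix proteases (-0.19) and of glycolysis and hypoxia (-0.14) reversed direction, far from any call. The interferon list ran from -0.22 (without Has-tKO 1, camera adjusted p = 0.0296) to 0.34 (without Has-tKO 4, 0.00283) with 1 library left out, so that its direction depends on single libraries. Camera calls of Notch, matrix protease, antigen presentation, glycolysis and mitochondrially encoded genes were each lost in 4 or more of these 8 fits, and that of proteoglycan core proteins in 1.

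Changed genes near the Has loci, 6 at first, were 0 without a filter, 18 with weights, 11 with scaling and without wildtype 1, 11 with scaling and without both libraries, 12 without both, 2 with scaling and block, and 15 with scaling and weights. A window of 5 Mb gave 2, a window of 20 Mb gave 14, and leaving out 1 library gave 0 to 11.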

Other observations

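In this part the comparisons of splits of the libraries were chosen only after the counts had been seen. The tests of dilution, of libraries that stand apart and of the myeloid rise were written before their own results. The patterns they address, the direction of the lists and the outlying libraries were already known by then.

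Factors that act on osteoclasts were higher in Has-tKO in part. Of 12 tested osteoclast-regulating factors 4 rose, namely Ccl2, the monocyte chemokine Ccl7 (87.0 ± 18.3 to 204 ± 45.4 FPKM, log2 fold change 1.22, SE 0.21, limma adjusted p = 0.0194, and 0.0631 after scaling), Tnfsf9 (0.76, adjusted p = 0.0384) and Csf1, the growth factor of macrophages and osteoclasts (54.9 ± 12.6 to 96.2 ± 7.26 FPKM, 0.83, adjusted p = 0.0485). After scaling 3 rose (Ccl2, Tnfsf9 and Csf1) and 2 fell (Wnt16 and Efnb2). Adjusted over the list alone 5 were higher and 2 lower, and camera gave an adjusted p of 0.222. Of 8 tested osteoclast markers none changed, while 2 were higher and 2 lower when adjusted over the list alone, against 0 higher and 2 lower after scaling (camera adjusted p = 0.598). The lower ones were tartrate-resistant acid phosphatase, Acp5 (-1.47, adjusted p = 0.0653), and the gelatinase Mmp9 (-1.23, adjusted p = 0.131), against the direction of the other myeloid markers.

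Of 28 tested p53 targets the stress cytokine Gdf15 (1.52, adjusted p = 0.0111) and the kinase Plk3 (2.07 ± 0.980 to 7.56 ± 2.22 FPKM, adjusted p = 0.0156) rose, and 4 were higher when adjusted over the list alone (camera adjusted p = 0.147). Of 16 tested glucocorticoid targets Dusp1, Errfi1 (1.57, adjusted p = 0.0219), Cebpd and Mt2 rose, and 5 were higher and 1 lower when adjusted over the list alone, against 5 and 3 after scaling (camera adjusted p = 0.290, fry adjusted p = 0.0462 against no change, and 0.142 after scaling, when only Errfi1 rose). Dusp1 lies within 10 Mb of the engineered Has1 locus. Of 15 tested IGF axis genes Igfbp3 (0.97, adjusted p = 0.0152) and Igf2 (0.72, adjusted p = 0.0392) rose and Htra1 fell, of which only Htra1 passed after scaling (Igfbp3 0.0611, Igf2 0.0580), with 4 higher and 1 lower when adjusted over the list alone, against 3 and 3 after scaling (camera adjusted p = 0.694). Further lists without a camera call had these changed genes: Igfbp3 and Ccn2 among 19 YAP and TEAD targets (0.678), Icam1 among 23 integrins and adhesion genes (0.101), Fam20c among 14 osteocyte markers (0.712), Cfp among 13 complement genes (0.898), Atf3 among 27 genes of the unfolded protein response (0.681), and, lower, Acot2 among 21 genes of fatty acid oxidation (0.695). Adjusted over the list alone these 6 lists had 4, 5, 1, 3, 1 and 1 higher and 1, 0, 0, 1, 0 and 1 lower members, and after scaling 3, 6, 3, 1, 2 and 0 higher and 1, 0, 2, 2, 1 and 2 lower members. Over all genes neither Igfbp3 nor Cfp passed after scaling, Tgfb2 fell among the YAP and TEAD targets, Cd59a fell among complement genes, and Itga4 and Alcam rose among adhesion genes.

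Chosen after the values were seen, 3 loci named as near-identical copies rose: Rnps1-ps (1.40 ± 0.752 to 13.9 ± 4.97 FPKM, log2 fold change 2.61, adjusted p = 0.00226), Atp6v0c-ps2 (48.0 ± 14.7 to 139.8 ± 17.6 FPKM, 1.56, adjusted p = 0.00633) and Hmga1b (2.63 ± 0.710 to 12.4 ± 1.08 FPKM). Their parents Hmga1 (-0.09, adjusted p = 0.896) and Rnps1 (-0.30, adjusted p = 0.423) did not change. Reads of copies are hard to place, and these levels are uncertain.

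Members of the osteoblast and chondrocyte lists had a median scaled log2 fold change of -0.44 (46 genes), against -0.05 for 71 other stromal genes. The difference of -0.39 (permutation p = 7.0e-05 over genes, which are not independent) pooled unlike lists. After scaling the median was -0.90 for chondrocyte markers, -0.28 for osteoblast commitment and -0.29 for osteoblast matrix and mineralization. Other stromal lists had -0.23 (fibrillar and basement membrane matrix), -0.13 (stromal progenitors) and 0.22 (contractile genes). For chondrocyte markers these values argue against an equal dilution of all stromal RNA by a larger myeloid share as the whole cause. By median the osteoblast lists lay close to the fibrillar matrix list, so the pooled test does not exclude equal dilution for them. Their members were less evenly split, however. Adjusted over the list alone after scaling, 1 rose and 5 fell for commitment, 2 and 7 for matrix and mineralization, and 7 and 8 for the fibrillar list. Fry after scaling gave adjusted p = 0.0270, 0.0255 and 0.476 in that order. Without wildtype 1 and Has-tKO 4 the median of the pooled osteoblast and chondrocyte members was -0.40. It lay below that of each of 100 random lists, which argues against these 2 libraries as the whole cause. A smaller share of skeletal precursors and a lower expression per cell were not told apart.

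The myeloid list stayed 0.76 to 1.03 above all tested genes whichever library was left out, which argues against a single library as the cause. The NF-kappaB and cytokine list minus the myeloid list gave -0.15 (permutation p = 0.398 over genes), so more myeloid cells in an unchanged state and an inflammatory state of the cells present could not be told apart. The abundant markers C1qb (161 ± 48.8 and 290.5 ± 80.4 FPKM) and Tyrobp (48.4 ± 9.03 and 81.0 ± 18.9 FPKM) were present in wildtype too.

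Among the 35 ways to split 8 libraries into 4 and 4, the genotype split was the only 1 with as many as 176 changed genes, and the highest other count was 1. After scaling it was again 1 split of 35 (280 against 2 at most), and 1 of 35 for genes changed at least 2-fold (114 against 1 at most). For gene lists 3 of 35 splits had as many calls as the 17 found, the genotype split among them. Wildtype 1 and 3 with Has-tKO 1 and 4 against the rest, a split even in genotype, had 18 (8 after scaling). Wildtype 1 with Has-tKO 1, 3 and 4 against the rest, which mostly follows genotype, had 18 (17 after scaling). Without scaling, camera calls of this number therefore also arose from a split that ignores the genotype. After scaling the genotype split had 16, splits even in genotype had 9 at most, and wildtype 1, 2 and 4 with Has-tKO 3 had 17.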
